A study of Mus musculus with 82 samples.

How the data were processed

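CUT&RUN libraries of mouse E14 cells were described by the labels as mESCs, EpiSCs or embryoid bodies of an NSD1-dTAG knock-in line, an Nsd1 knockout line (KO2), the knockout with rescue constructs and a SETD2-dTAG line, with dTAG-13 at 500 nM where cells were treated. The 82 samples fell into 73 groups by cell type, line, treatment and target. Per the submitters' processing notes, reads were made with bcl2fastq 2.20.0.422, aligned with Bowtie2 2.3.4.1 to the mouse genome (mm10), handled with SAMtools 1.9 and deepTools 3.2.1, and peaks were called with MACS2 2.2.6.

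The values came from 10 deposited peak lists in narrowPeak form. Each line gave the interval, the deposited score, the authors' fold enrichment at the summit, the authors' -log10 p and -log10 q, and the summit offset. The deposited score was 10 times the authors' -log10 q, as a whole number, in 100% of the lines of 9 lists and 99.9% of those of H3K4me1. Controls and thresholds differed between lists and are given by the file names. An IgG library and a q of 0.05 served 6 lists, namely H3K27ac, H3K4me1, MED1, BRD4 and both H3K27me3 lists. The NSD1 list of mESCs was called with no control at a q of 1e-06, the NSD1 list of EpiSCs against cells treated with dTAG-13, and the pooled H3K36me2 and NSD1-C lists against the knockout. The pools held 4 and 2 libraries. The name of the NSD1-C file carries serum, those of most others 2i. No replicate numbers are carried by the lists, no read counts are given, and the depth per sample is therefore unknown, so that the number of peaks is the only measure of precision. Other samples and file types were not used here.

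Peaks on chromosomes 1 to 19 and X were analysed, and those on Y and unplaced contigs were counted apart. Intervals were converted to 1-based positions. Genes came from a RefSeq table of GRCm38.p6 with 21631 protein-coding genes. It holds no strand, so windows were placed around both ends of each gene, 1 kb either side for peaks and 5 kb for gene lists. This replaced the start sites planned before the data were examined. The tests, alternatives, gene lists and naming rule had been fixed before the data were examined, except where the text says otherwise.

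An overlap required 1 bp. For each pair of lists, the first was rotated along each chromosome by a random offset that wrapped at the ends, 1000 times with seed 20240. The number of overlapping peaks was divided by the rotation mean, and the two-sided permutation p was adjusted by Benjamini-Hochberg over 32 tests. Shares carry exact Clopper-Pearson 95% intervals. Distal H3K4me1 peaks lay over 2.5 kb from any gene end. H3K27me3 lists were compared by covered length, by shared peaks and by the length covered within 5 kb of gene ends, with no test between genotypes.

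The 16 gene lists were naive, general and formative or primed pluripotency, mesendoderm, neuroectoderm, trophoblast, Hox, H3K36 methylation enzymes, Polycomb complexes, DNA methylation, enhancer cofactors, germline, imprinted, housekeeping, and neuronal and liver or immune controls. They matched 273 members, while 5 (H19, Kcnq1ot1, Meg3, Rian and Peg13) were not among the protein-coding genes. Each share was ranked among 10000 random lists drawn with replacement within deciles of gene length. The direction of genes that differed between lists was compared with that of all other genes by Fisher's exact test, two-sided, adjusted over the 16 lists. Genes were named as members of these lists, as the nearest protein-coding gene within 100 kb of the 12 peaks of largest authors' fold enrichment in each class, or as the 12 genes with the largest increase or decrease in H3K27me3 length.

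Alternatives were a summit inside the other peak, 50% of the peak covered, the stronger 50% of each list by the authors' q, a q of 1e-06 or less, uniform placement, rotation by 20 kb to 1 Mb, every contig, windows of 2.5 kb, all annotated genes, a distal limit of 5 kb, joining within 1 kb, and the same number of H3K27me3 peaks. Leaving out the strongest 1% of each list was added after the data were seen.

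The methods were tested on simulated data. Lists of 1995 peaks with 10%, 30% and 60% of peaks planted on H3K27ac gave 12.1%, 31.6% and 61.1%, against 2.42% to 2.45% at random, and 2.5% of 200 runs with no planted peaks had a permutation p of 0.05 or less. Simulated NSD1 lists with distal ratios of 0.998 and 2.41 had rotation means of 2.09 and 2.13, so the rotation mean of that ratio was not 1. Random lists of 20 genes gave 3.25% of shares outside the central 95%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.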

Results

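Chromatin of mouse E14 cells was profiled by CUT&RUN, in which an antibody directs a nuclease to its target and the released DNA is sequenced. The labels describe 82 samples in 73 groups, of which 73 samples came from embryonic stem cells (mESCs), 3 from epiblast stem cells (EpiSCs, a primed pluripotent state) and 6 from embryoid bodies. By target, 15 samples were made with an HA antibody against tagged NSD1, a histone H3 lysine 36 methyltransferase, and 18 against dimethylated lysine 36 (H3K36me2). A further 7 samples were made against H3K27me3, the Polycomb mark, 6 against H3K27ac and 5 against H3K4me1, marks of active and of primed or active enhancers, and 4 each against the coactivators MED1 and BRD4. The lines were NSD1-dTAG knock-in cells (61 samples), in which NSD1 carries a tag that lets the compound dTAG-13 degrade it, an Nsd1 knockout line (4 samples), the knockout with a rescue construct (10 samples) and SETD2-dTAG cells (7 samples).

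Processed values took the form of 10 peak lists, and the comparisons rest on these. Of the lists, 8 came from a single library each, the H3K36me2 list from a pool of 4 libraries and the list of the rescue construct labelled NSD1-C from a pool of 2. On chromosomes 1 to 19 and X, NSD1 had 34489 peaks in untreated NSD1-dTAG mESCs and 20772 in untreated NSD1-dTAG EpiSCs, and NSD1-C had 1995 peaks in knockout mESCs. H3K36me2 had 6607 peaks, H3K27ac 43217, H3K4me1 145675, MED1 3108 and BRD4 6816, all in untreated NSD1-dTAG mESCs. H3K27me3 had 96726 peaks in those cells and 145450 in the knockout. The lists give intervals and peak statistics but no read counts, so the depth of each library is unknown. No value has replicates behind it. Shares of peaks are given with exact (Clopper-Pearson) 95% intervals in brackets, which treat peaks as independent, take no account of duplicate reads from PCR, and cover counting error only. Fold enrichment and q of a peak are the authors' values.

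The first question was where NSD1 sits in mESCs relative to enhancers. Of the 34489 NSD1 peaks, called with no control library, 92.9% [92.6 to 93.1] overlapped H3K4me1 and 40.5% [39.9 to 41.0] overlapped H3K27ac, whereas random placement gave 12.7% and 3.01%. MED1, a Mediator subunit, lay under 6.40% [6.15 to 6.67] of NSD1 peaks against 0.209% at random, and BRD4, a reader of acetylated histones, under 14.7% [14.3 to 15.1] against 0.442%. Most NSD1 peaks lay away from genes' ends: 26.8% were within 1 kb of an end of a protein-coding gene, 34.0% elsewhere inside a gene and 39.2% outside genes. Grouped by the authors' q, the strongest peaks carried the most enhancer marks. NSD1 peaks were divided into 5 groups of equal size by the authors' q. From the weakest to the strongest group, the share on H3K27ac rose from 24.6% to 63.8%, on BRD4 from 6.41% to 31.9% and on H3K36me2 from 4.07% to 26.8%, while the share on H3K27me3 fell from 14% to 3.49%.

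Each overlap was compared with 1000 random rotations of the NSD1 list along its chromosomes, a permutation of positions that keeps peak widths and spacing. The observed number of overlapping peaks was 13.4 times the rotation mean for H3K27ac, 7.30 times for H3K4me1, 30.6 times for MED1, 33.3 times for BRD4 and 6.07 times for gene ends. Each two-sided permutation p was 0.002, the smallest that these rotations can give, and 0.0021 after Benjamini-Hochberg adjustment over the 32 rotation tests. With rotation by at most 1 Mb, which keeps regional gene density, the ratios were 4.60 for H3K4me1 and 18.5 for MED1, and counting a MED1 overlap only where the NSD1 summit lay inside it gave 52.0. The annotation used carries no strand, so both ends of each gene were used in place of start sites. With windows of 2.5 kb the gene-end ratio was 3.83, and with all annotated genes it was 3.79.

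The NSD1 peaks of largest fold by the authors' values were narrow. They included a peak of 352 bp inside Kctd16, which encodes an auxiliary subunit of GABA-B receptors (chromosome 18, 40308024 to 40308375, mm10), with a fold of 28.3 and with H3K27ac, H3K4me1, MED1, BRD4, H3K36me2 and NSD1-C peaks at the same place. Others, such as a peak of 328 bp on chromosome 4 (64497734 to 64498061, fold 31.0) and one inside Cntnap5b on chromosome 1 (100180097 to 100180376, fold 29.3), overlapped no other list. Only the peaks at Kctd16, Fam107a and Aida, among the 12 of largest fold, carried H3K27ac or H3K4me1. The largest folds therefore did not follow the rise in enhancer marks seen over groups by q. The largest MED1 folds lay near 1700018B08Rik and Arl4d (50.8 and 49.4). Another of the 12 largest was inside Esrrb, an orphan nuclear receptor gene of naive pluripotency (chromosome 12, 86500316 to 86505434, fold 44.6), and others were beside the histone genes H4c18, H4c17, H1f2 and H4c1 on chromosome 13 (folds 48.9, 48.1, 47.6 and 38.6). All 5 of these MED1 peaks overlapped NSD1, H3K27ac and BRD4, as did the peak near Klf9. The others of the 12 did not overlap all of these lists, and those at 1700018B08Rik and Trpv4 overlapped none of them. Among the largest BRD4 folds were peaks near Smarcad1, a chromatin remodeller gene (chromosome 6, 65019945 to 65026166, fold 41.2), and Pdk1, a kinase gene of pyruvate metabolism (chromosome 2, 71866726 to 71869091, fold 29.3), both with NSD1, MED1 and H3K36me2 peaks.

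Distal H3K4me1 peaks, over 2.5 kb from any gene end, were used to compare bound with unbound enhancers. Of 94750 such peaks, 16443 overlapped NSD1, and 46.9% [46.2 to 47.7] of these carried H3K27ac. Among the 78307 without NSD1, 10.8% [10.5 to 11.0] did, a ratio of 4.36 against 1.63 (range 1.45 to 1.98) when the NSD1 list was rotated (permutation p = 0.002). Rotation does not give the ratio of a list without preference for H3K27ac. A simulated list of that kind had a ratio of 0.998 and a rotation mean of 2.09. The permutation p therefore compares the NSD1 list with rotated lists only and does not test bound against unbound enhancers. Wide H3K4me1 peaks are hit more often and carry H3K27ac more often, so the comparison was repeated within 5 groups of peak width of equal size, a step chosen after the data were seen. The ratio was 6.85 in the narrowest group, then 5.71, 4.31 and 2.32, and 1.84 in the widest.

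**Figure D1:**
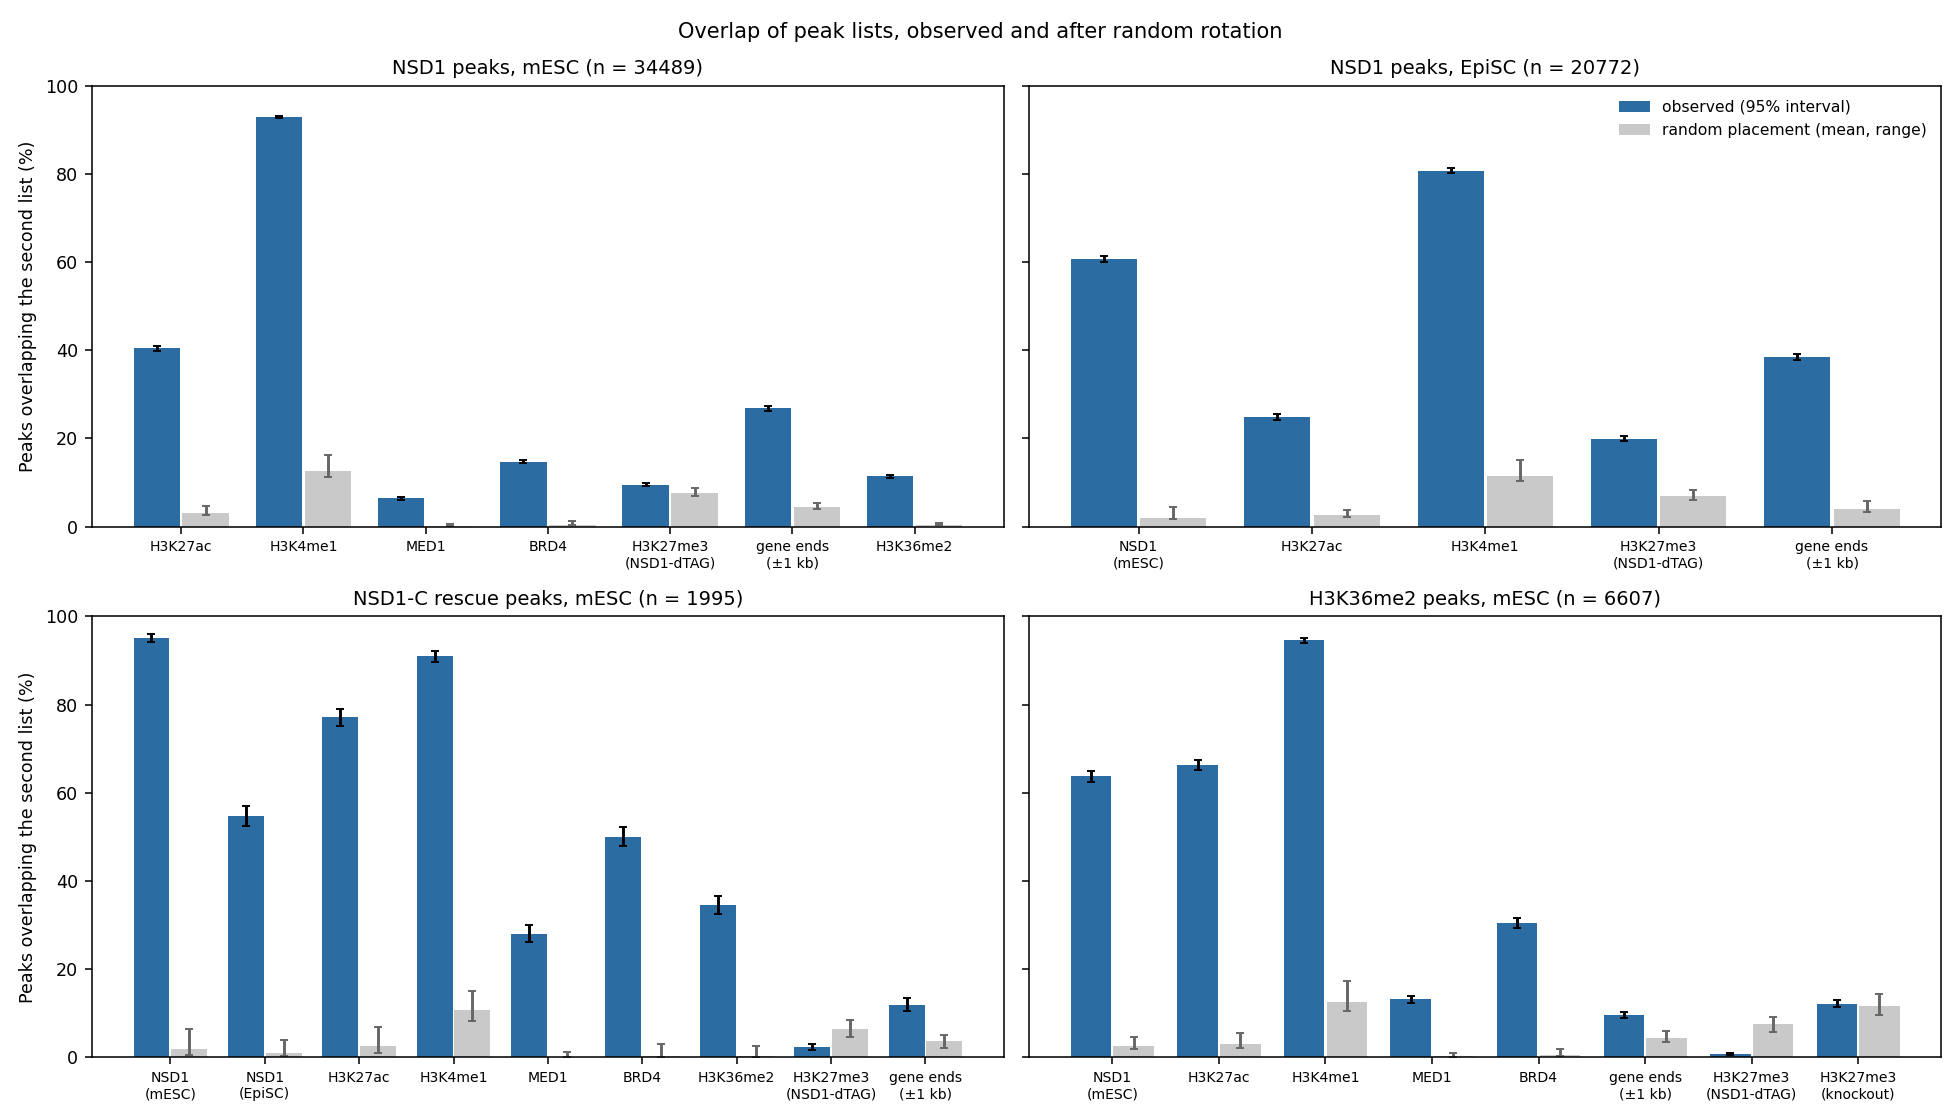
Share of peaks of 4 lists (panels) that overlap each other list, in percent of the peaks of the panel's list, with exact 95% intervals (blue) and the mean and range over 1000 random rotations (grey). The NSD1 and H3K36me2 lists of mESCs exceed their random range at H3K27ac, H3K4me1, MED1 and BRD4, and H3K36me2 falls below it at H3K27me3 of NSD1-dTAG cells (0.696% against 7.47%).

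NSD1 and H3K27me3 overlapped at 9.54% [9.23 to 9.85] of NSD1 peaks, against 7.60% at random, a ratio of 1.25 (permutation p = 0.002). This direction was not stable. With the stronger 50% of each list the ratio was 0.915 (permutation p = 0.0699), and with rotation by at most 1 Mb it was 0.886 (permutation p = 0.002).

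Gene lists fixed in advance were examined next, counting a gene as marked when a peak lay within 5 kb of either end. Among 20 naive pluripotency genes, 18 carried an NSD1 peak in mESCs, including Nanog, Klf2, Klf4 and Tfcp2l1, transcription factor genes of the naive state. Of the same genes, 13 carried H3K36me2, 19 H3K27ac, 12 MED1 and 12 BRD4. All 12 general pluripotency genes carried NSD1, among them Pou5f1, which encodes OCT4, and Sall4, and 11 carried H3K27ac, 7 MED1, 8 BRD4 and 4 H3K36me2. Among 22 genes of the Polycomb complexes, 21 carried NSD1, including Eed, Suz12 and Ezh2, the core of the H3K27 methyltransferase complex, and 6 carried H3K36me2. Among 14 enhancer cofactor genes 13 carried NSD1, among 13 H3K36 methylation enzyme genes 10 did, Nsd1 itself among them, and among 15 housekeeping genes 11 did. NSD1 was carried by 5 of 20 neuroectoderm genes, 2 of 14 neuronal control genes and 3 of 15 liver and immune control genes. Among the other lists rich in H3K27me3, it was carried by 12 of 20 mesendoderm, 9 of 12 trophoblast, 15 of 39 Hox and 6 of 14 germline genes, and differences between lists were not tested.

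Each list was ranked among 10000 random lists of genes of matched length. NSD1 in mESCs ranked at percentile 99.9 for the naive list (90% against a random mean of 57.1%) and above 99 for the general pluripotency, Polycomb and enhancer cofactor lists. The percentiles were 0.26 for the neuroectoderm list, 0.01 for the neuronal and 0.28 for the liver and immune control lists. Over 16 lists and 12 peak sets, 73 of 192 shares lay outside the central 95% of random lists, against a nominal 9.6. Random lists of 20 genes gave 3.25% of shares outside, fewer than nominal. The peak sets overlap, so the 192 shares are not independent. With the stronger 50% of each peak list, NSD1 at the Polycomb list fell to percentile 95.8 and at the enhancer cofactor list to 77.3. H3K36me2 at the general pluripotency list fell to 97.1 with that setting and to 85.1 with peaks of q 1e-06 or less.

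The comparison of EpiSCs with mESCs asked how NSD1 sites differ between primed and naive cells. Of the 20772 EpiSC peaks, 60.7% [59.995 to 61.3] overlapped an mESC peak, 29.6 times the rotation mean (permutation p = 0.002). Over the alternatives the ratio ranged from 20.3 to 48.3, the latter when 50% of the EpiSC peak had to be covered, and it was 47.5 by summit. Shared sites lay at gene ends more often: 49.7% of the 12202 mESC peaks found in both lists did, against 14.3% of the 22287 found in mESCs alone. The mESC peaks absent from the EpiSC list carried H3K27ac at 41.9% [41.3 to 42.6]. The 8171 EpiSC peaks absent from the mESC list lay on chromatin that, in mESCs, carried H3K27ac at only 9.89% [9.25 to 10.6] and H3K27me3 at 30.3% [29.3 to 31.3]. For EpiSC peaks shared with mESCs the corresponding shares were 34.6% and 13.3%. All marks in this comparison were measured in mESCs.

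Gene lists differed in which cell state carried NSD1 more often. Among 19 formative and primed epiblast genes, 18 carried NSD1 in EpiSCs and 13 in mESCs. The genes marked in EpiSCs alone were Fgf5, a classical marker of the primed epiblast, Pou3f1, which encodes OCT6, Cdh2, which encodes N-cadherin, Sox3 and Krt18. Among 20 neuroectoderm genes, 15 carried NSD1 in EpiSCs against 5 in mESCs, and 11 were marked in EpiSCs alone, including Pax6, Neurog2 and Six3, transcription factor genes of the developing nervous system. En2 was marked in mESCs alone. Among 20 mesendoderm genes the counts were 16 in EpiSCs and 12 in mESCs, and among the neuronal control genes 7 and 2. The Hox and trophoblast lists had fewer marked genes in EpiSCs than in mESCs, with 11 and 15 of 39 Hox genes and 8 and 9 of 12 trophoblast genes. The same held for 15 and 21 of 22 Polycomb genes and 10 and 13 of 14 enhancer cofactor genes. The naive genes also had fewer, with 11 marked in EpiSCs, and 8 of the 20 were marked in mESCs alone, among them Klf4, Zfp42, Nr0b1, Dppa2 and Dppa4. None of the 15 liver and immune control genes carried NSD1 in EpiSCs.

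These directions were tested against all other protein-coding genes, of which 27% to 27.2% of those marked in a single state were marked in EpiSCs alone, a test chosen after the data were seen. By Fisher's exact test, two-sided and adjusted over the 16 lists, the direction differed for the neuroectoderm list (adjusted exact p = 8.16e-05), the formative list (0.0113), the neuronal control list (0.0113) and the mesendoderm list (0.0261). For the naive list it did not (adjusted exact p = 0.682). The neuroectoderm and formative calls held in each of the 3 alternative settings that alter these NSD1 values, with adjusted exact p values up to 0.00276 and 0.0223. The mesendoderm call ended with windows of 2.5 kb, with the stronger 50% of peaks and with q of 1e-06 or less (0.113, 0.919 and 0.774), and the neuronal call with the latter pair (0.919 and 0.636). Both lists were called with different controls and thresholds, so a peak in a single list is not a site shown to be gained or lost. The EpiSC list was called against cells treated with dTAG-13, but the sample labels include no treated EpiSCs. Whether that control matched the cell state could not be checked. Background present in EpiSCs alone is therefore not excluded for genes marked only there.

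**Figure D2:**
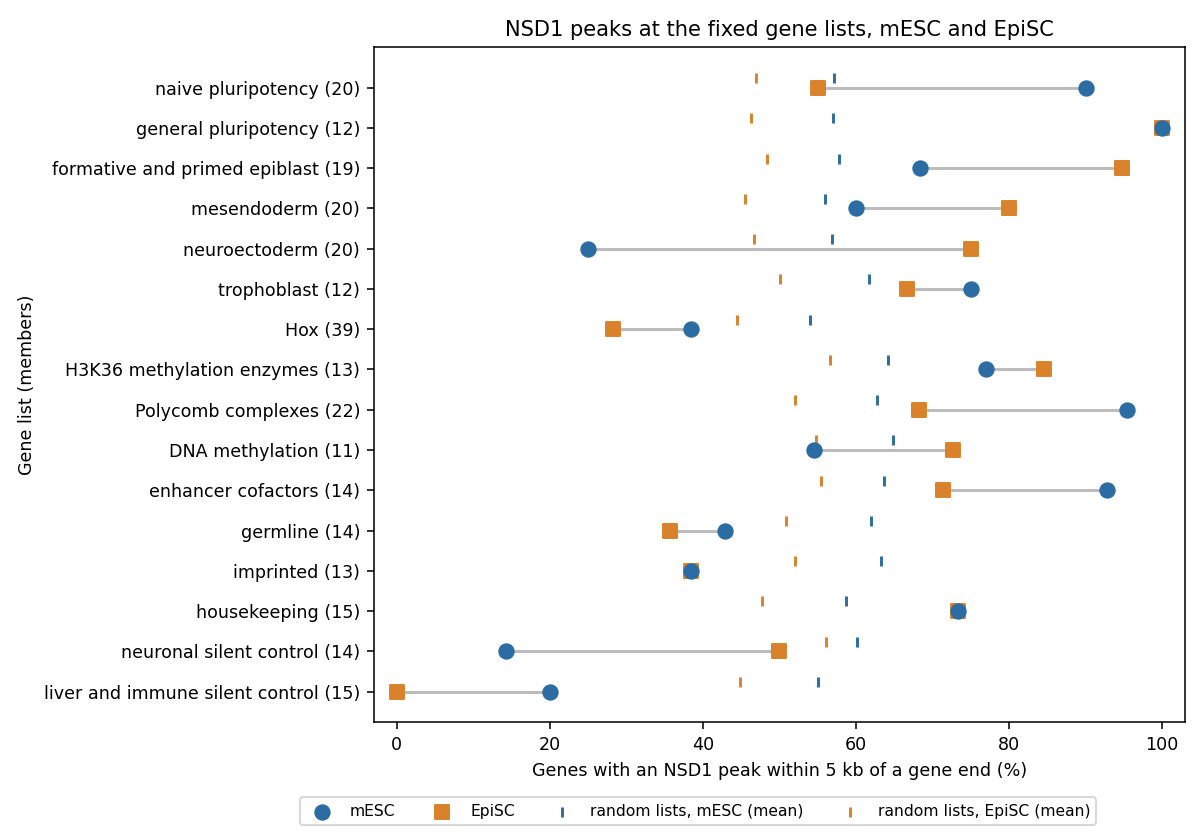
Share of the genes of each fixed list (number of members in brackets) with an NSD1 peak within 5 kb of a gene end, in percent, in mESCs (blue circles) and EpiSCs (orange squares), with the mean of random lists of matched length as ticks. The neuroectoderm list stands at 25% in mESCs and 75% in EpiSCs, and the naive list at 90% and 55%, a direction that did not differ from other genes.

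Among EpiSC sites shared with mESCs, the largest fold was at Ndufs8, which encodes a subunit of respiratory complex I (chromosome 19, 3912068 to 3913132, fold 24.4), and another was inside Gulp1 (chromosome 1, 44613001 to 44614185, fold 21.2), both on H3K27ac and H3K4me1 of mESCs. The 12 largest shared folds also included sites at Gse1, Frem2 and Zmiz1 on H3K27me3 of NSD1-dTAG mESCs. Among sites absent from the mESC list, the largest was inside Septin9, a cytoskeletal gene (chromosome 11, 117278043 to 117278935, fold 19.6), where both H3K27me3 lists had a peak, the only site among the 12 largest of this class on H3K27me3 of NSD1-dTAG cells. Others were inside Nalcn, a sodium leak channel gene (chromosome 14, 123552607 to 123553651, fold 14.3), and Grm1, a glutamate receptor gene (chromosome 10, 10996474 to 10997494, fold 13.97), the latter on H3K27ac and H3K4me1.

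The NSD1-C rescue list was called against the knockout line, so it offers NSD1 sites with a control that lacks NSD1. Of its 1995 peaks, 95.2% [94.2 to 96.1] overlapped an NSD1 peak of NSD1-dTAG mESCs and 54.7% [52.5 to 56.9] one of EpiSCs. Of the same peaks, 77.1% [75.2 to 78.9] lay on H3K27ac, 50.1% [47.9 to 52.3] on BRD4, 28.0% [26.1 to 30.0] on MED1 and 34.5% [32.4 to 36.7] on H3K36me2. Only 2.26% [1.65 to 3.01] lay on H3K27me3 and 11.9% at gene ends. The largest folds were inside Sntg1, which encodes a syntrophin (chromosome 1, 8581276 to 8582573, fold 20.2), inside Ppp2r5c, a phosphatase subunit gene (chromosome 12, 110471306 to 110473517, fold 18.0), and near Pole4, a DNA polymerase subunit gene (chromosome 6, 82687181 to 82689070, fold 17.8). All of these also carried NSD1 in both cell states, H3K27ac and BRD4. Peaks of NSD1-C with no NSD1 peak in mESCs had smaller folds, up to 7.12 at H2ac12, a histone gene.

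The overlap with NSD1 was 50.9 times the rotation mean, with H3K27ac 31.4 times, with BRD4 149 times and with H3K27me3 0.354 times (permutation p = 0.002 each). Over the alternatives the ratios ranged from 35.1 to 82.2 for NSD1, 20.0 to 54.7 for H3K27ac, 72.5 to 218 for BRD4 and 0.165 to 0.364 for H3K27me3, all in the same direction. The file of this list names serum medium, whereas the NSD1 list of mESCs names 2i, so construct, line and medium differ together between these lists.

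H3K36me2, the product of NSD1, was compared with NSD1 and enhancer marks in untreated NSD1-dTAG mESCs. The H3K36me2 list was called against the knockout, so it holds sites where the mark exceeded that of the knockout. The shares below describe such sites and not all H3K36me2. Of 6607 H3K36me2 peaks, 63.7% [62.5 to 64.9] overlapped NSD1, 66.3% [65.1 to 67.4] H3K27ac, 94.6% [94.0 to 95.1] H3K4me1, 30.5% [29.4 to 31.6] BRD4 and 13.1% [12.3 to 13.98] MED1. Most lay outside genes (68.3%), and 9.61% at gene ends. The median distance between an H3K36me2 summit and the nearest NSD1 summit was 620 bp, and 96.6% had one within 10 kb. H3K36me2 peaks with NSD1 carried H3K27ac at 77.6% [76.3 to 78.9] and BRD4 at 42.5% [41.0 to 44.1], and those without NSD1 at 46.4% [44.4 to 48.5] and 9.30% [8.17 to 10.5]. Outside a block on chromosome X, the largest folds at NSD1 sites lay near Clybl (chromosome 14, 122414938 to 122417709, fold 10.8), Etnk1 (chromosome 6, 143154536 to 143160373, fold 10.7) and Ect2, a regulator of cytokinesis (chromosome 3, 27154083 to 27156539, fold 10.3). Further such sites lay near Tle4, a corepressor gene, Pim1, a kinase gene, and Sgk1, another kinase gene (folds 9.84, 9.42 and 9.39), and each of these 6 sites carried H3K27ac, H3K4me1 and BRD4. The 12 largest H3K36me2 folds on chromosomes 1 to 19 and X included 11 in the X block, where 2.41% of H3K36me2 peaks overlapped NSD1.

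The overlap of H3K36me2 with NSD1 was 25.97 times the rotation mean and with H3K27ac 22.1 times (permutation p = 0.002 each). The first ratio ranged from 15.9 with rotation by at most 1 Mb to 39.3 by summit, and the other from 13.3 with that rotation to 38.5 with q of 1e-06 or less. Naive, formative and housekeeping genes carried H3K36me2 at 65%, 42.1% and 33.3% against random means of 6.11%, 5.94% and 6.09%, each beyond percentile 99.9.

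H3K27me3 lists of NSD1-dTAG and knockout mESCs were compared to ask where the Polycomb mark differs without NSD1. The knockout list covered 189.4 Mb against 117.1 Mb, a ratio of 1.62, with mean peak widths of 1302 bp and 1211 bp. Of the knockout peaks, 38.6% overlapped an NSD1-dTAG peak, and 61.0% of the NSD1-dTAG peaks overlapped a knockout peak. Among 21631 protein-coding genes, 8391 carried H3K27me3 within 5 kb of an end in both lists, 2429 in the knockout alone and 984 in NSD1-dTAG cells alone. With the same number of peaks from each list the length ratio was 1.41. Each genotype had 1 list, so no test between genotypes was possible and the values below describe these lists.

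The 12 genes with the largest added H3K27me3 length in the knockout were led by Cdx1, a homeobox gene of posterior development (chromosome 18, 61018862 to 61036199), where 0 bp were covered in NSD1-dTAG cells and 16770 bp in the knockout, in a window of 20002 bp. Gmfg-ps on chromosome 6 (4893256 to 4903214) had 0 bp and 16490 bp and carried NSD1, H3K36me2 and H3K27ac in NSD1-dTAG cells. Sting1, an innate immune sensor gene (0 bp and 16098 bp), Rab31, a small GTPase gene (0 bp and 15284 bp), and Pmepa1, a gene of TGF-beta signalling (640 bp and 15775 bp), were also among the 12. Of these 12 genes, 10 carried NSD1, 2 carried H3K36me2 (Gmfg-ps and Pmepa1) and 4 carried H3K27ac, and Sting1 carried none of these. The map of the Gmfg-ps region was drawn because this gene had the largest added length among those with H3K36me2. The 12 genes with the largest reductions included Grin1, which encodes an NMDA receptor subunit (15985 bp and 1350 bp), Sox21, a neural transcription factor gene (12164 bp and 0 bp), Cdkn2a, which encodes the cell cycle inhibitors p16 and p19 (9807 bp and 0 bp), and Nes, which encodes nestin (18283 bp and 8619 bp). Of these 12 genes, 8 carried NSD1 and 0 carried H3K36me2 or H3K27ac. Of all protein-coding genes, 57.8% carried NSD1, 6.37% H3K36me2 and 30.2% H3K27ac. Genes with large reductions were picked for long H3K27me3 in NSD1-dTAG cells, which overlapped only 0.696% of H3K36me2 peaks. The difference in these marks between both sets of 12 genes may therefore follow from how they were picked. Cdx1 and Gm52351, both with H3K27ac, also overlap each other.

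**Figure D3:**
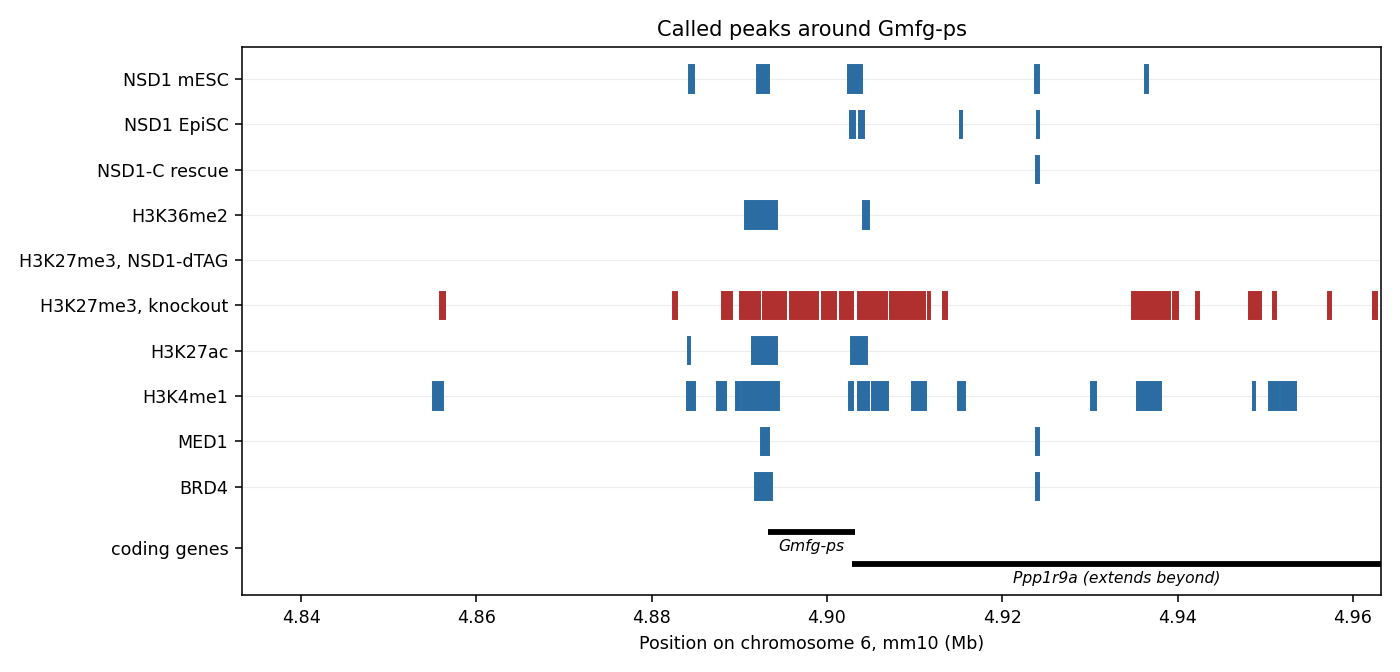
Called peaks of each list around Gmfg-ps on chromosome 6 of mm10 (position in Mb), with protein-coding genes as bars below and knockout H3K27me3 in red. H3K36me2 covers 4890668 to 4894265 beside NSD1, H3K27ac, MED1 and BRD4 peaks, and H3K27me3 peaks appear in the knockout list alone.

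Covered length was compared at developmental genes. All 20 neuroectoderm genes and all 39 Hox genes carried it in both, as did 18 and 19 of 20 mesendoderm genes in NSD1-dTAG and knockout cells, 16 of 19 formative genes in each and 11 of 12 trophoblast genes in each. The formative members differed, since Otx2 was covered in NSD1-dTAG cells alone and Etv5 in the knockout alone. Over the neuroectoderm windows the covered share was 82.7% in NSD1-dTAG cells and 73.9% in the knockout, and 18 of the 20 genes were shorter in the knockout, where coverage fell by 9664 bp at Nes, fell by 2341 bp at Tlx3 and fell by 2220 bp at Lmx1b. Over the Hox windows it was 92.0% and 89.6%, and 29 of 39 genes were shorter. Trophoblast windows went from 39.9% to 52.4%, with Gcm1, a trophoblast transcription factor gene, at 4389 bp and 15983 bp. By Fisher's exact test against all other genes, of which 59.6% of those that differed were longer in the knockout, the direction differed for the neuroectoderm list (adjusted exact p = 4.76e-05) and the Hox list (4.76e-05), and for none of the other 14. Windows that are mostly covered can mainly shrink. Among windows at least 50% covered in NSD1-dTAG cells, the neuroectoderm call held (0 longer and 18 shorter, against 32.8% longer elsewhere, adjusted exact p = 0.0226) and the Hox call ended (adjusted exact p = 0.529). This cut did not match coverage with the other genes, and neuroectoderm windows were 82.7% covered. The limit on growth is therefore reduced but not removed. Both tests were chosen after the data were seen, and Hox neighbours share windows.

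H3K27me3 of NSD1-dTAG cells was carried by 3 of 20 naive genes, 3 of 12 general pluripotency genes, 2 of 15 housekeeping genes and 3 of 13 H3K36 methylation enzyme genes, with the general list at percentile 12.9, within the central 95% of random lists. In the knockout 8, 3, 3 and 4 did. Of the naive genes, 6 carried H3K27me3 in the knockout list alone (Klf5, Tbx3, Nr5a2, Dppa5a, Dppa2 and Sox2), with 274 bp at Sox2 to 1915 bp at Tbx3 covered. This share of 30% ranked at percentile 99.1 of random lists. The call ended with windows of 2.5 kb (percentile 85.4), with the stronger 50% of peaks (92.1) and with q of 1e-06 or less (61.6).

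Among the remaining lists, 10 of 14 germline genes carried H3K27me3 in each genotype, 7 and 9 of 13 imprinted genes did in NSD1-dTAG and knockout cells, and 5 and 6 of 11 DNA methylation genes did. The counts were 7 and 9 for the 22 Polycomb genes, 5 and 7 for the 14 enhancer cofactor genes, 12 and 12 for the 14 neuronal control genes and 10 and 9 for the 15 liver and immune control genes. NSD1 in mESCs and EpiSCs marked 6 and 5 germline genes, 5 and 5 imprinted genes, and 6 and 8 DNA methylation genes.

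The last comparison asked whether H3K27me3 lies on H3K36me2 sites, since methylated lysine 36 is known to hinder methylation of lysine 27 on the same histone tail. These sites were called against the same knockout line, so they were selected for less H3K36me2 in it. In NSD1-dTAG cells H3K27me3 overlapped 0.696% [0.510 to 0.928] of the H3K36me2 peaks, against 7.47% at random, a ratio of 0.0932 (permutation p = 0.002). The ratio was 0.0544 with the stronger 50% of peaks and 0.0290 with q of 1e-06 or less. In the knockout list the share on the same sites was 12.1% [11.3 to 12.9], against 11.7% at random, a ratio of 1.04 (permutation p = 0.5355). With rotation by at most 1 Mb that ratio was 0.636 (permutation p = 0.002), and with q of 1e-06 or less 0.747 (permutation p = 0.016). With the stronger 50% of peaks it was 0.898 (permutation p = 0.2517). Of the 89275 knockout peaks absent from the NSD1-dTAG list, 0.765% lay on H3K36me2 sites against 0.439% at random, a ratio of 1.74 (permutation p = 0.002). Part of this excess follows from the split, since H3K27me3 of NSD1-dTAG cells avoided H3K36me2 and the whole knockout list was at 1.04. Rotation by at most 1 Mb reduced it to 1.05 (permutation p = 0.4715).

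H3K27ac peaks of NSD1-dTAG cells were then divided by overlap with an H3K36me2 peak of those cells, called over the knockout. This comparison was added after the data were seen. H3K27me3 of NSD1-dTAG cells lay on 0.104% of the 3839 H3K27ac peaks with H3K36me2 and on 0.140% of the 39378 without. H3K27me3 of knockout cells lay on 8.13% [7.28 to 9.04] of those with H3K36me2 and on 2.14% [2.00 to 2.29] of those without. Among the latter the share was 3.67% [3.33 to 4.03] where NSD1 was present and 1.51% [1.37 to 1.66] where it was not. Within each of 5 groups of H3K27ac width the share with H3K36me2 was 4.13 to 4.59 times that without. With at least 50% of the H3K27ac peak covered the shares were 4.19% and 1.46%, and with q of 1e-06 or less 2.72% and 0.883%.

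**Figure D4:**
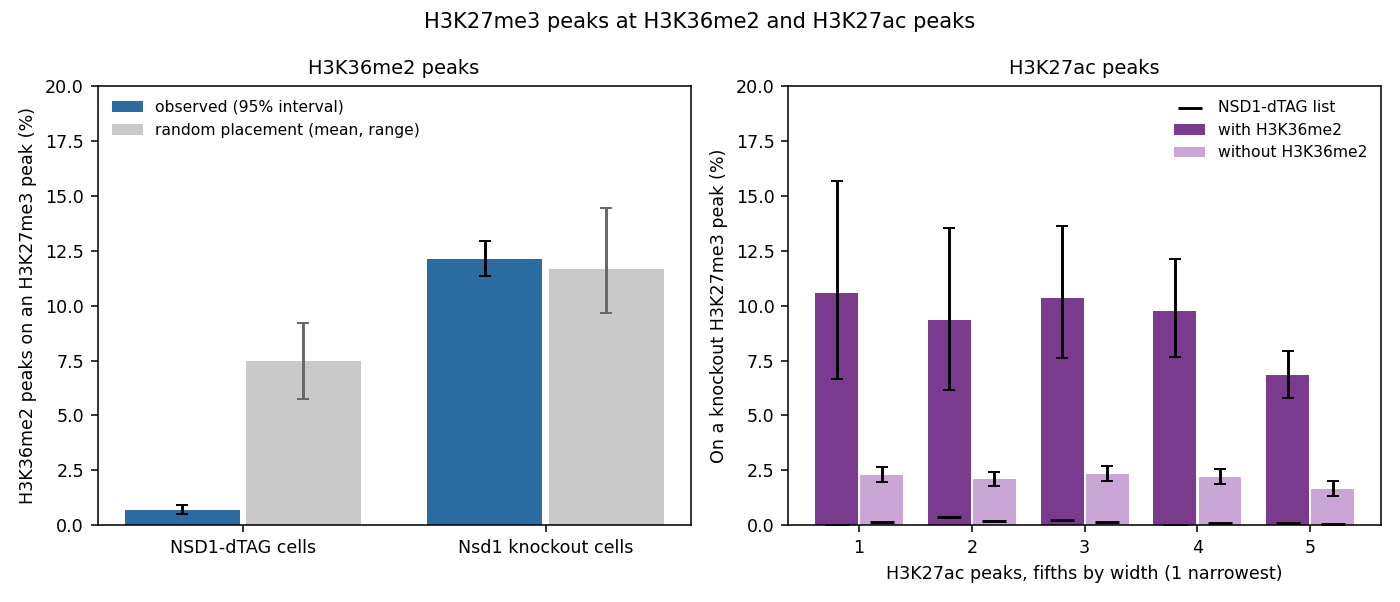
Left, share of H3K36me2 peaks on H3K27me3 of each genotype, in percent, with exact 95% intervals and the mean and range of random rotations. Right, share of H3K27ac peaks on knockout H3K27me3 in 5 groups of width, with and without H3K36me2 (exact 95% intervals), with NSD1-dTAG values as black ticks, and with H3K36me2 the share lies above that without in every group.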

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

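Of the tests in this part, those on a uniform gain over active chromatin, on the cell lines, on open chromatin background and on the X block were chosen only after the results were seen.

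Peaks outside chromosomes 1 to 19 and X drew attention as signal outside the reported values, used only in the alternative with every contig. With that alternative the ratio of NSD1-C went from 172 to 55.5 for MED1, 98.2 to 31.4 for H3K36me2 and 149 to 72.5 for BRD4. On unplaced or unlocalised contigs there were 56 peaks for NSD1 in mESCs, 31 for NSD1 in EpiSCs, 32 for NSD1-C, 53 for H3K36me2, 101 and 24 for H3K27me3 in NSD1-dTAG and knockout cells, 13 for H3K27ac, 50 for H3K4me1, 32 for MED1 and 25 for BRD4. On chromosome Y there were 62, 21 and 9 peaks for NSD1 in mESCs, NSD1 in EpiSCs and NSD1-C, 21 and 13 for H3K27me3 in NSD1-dTAG and knockout cells, 29 for H3K27ac, 114 for H3K4me1, 22 for MED1 and 21 for BRD4. The largest H3K36me2 fold on a contig was 43.1. No explanation of these peaks was tested.

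H3K27me3 of knockout cells lay on 12.1% of H3K36me2 sites, against 0.696% in NSD1-dTAG cells. More calls in the knockout list are not the whole cause, since with the same number of peaks from each list the share was 9.99% [9.28 to 10.7]. A gain uniform over active chromatin would not alone give this pattern. H3K27ac peaks with H3K36me2 had at least 4.13 times the share of those without in each of 5 groups of width. Only width was matched, and 68.3% of H3K36me2 peaks lay outside genes, against 25.8% of H3K27ac peaks. A gain that varies with position in genes is therefore not excluded. Spreading from neighbouring H3K27me3 may contribute but was not decided. Of the sites on knockout-only H3K27me3, 27.2% [23.9 to 30.6] lay within 10 kb of an NSD1-dTAG H3K27me3 peak, against 12.2% [11.3 to 13.03] of other sites. Knockout-only peaks touch no NSD1-dTAG peak, so knockout peaks that extend from such a peak are left out of the first group. Regional density of H3K27me3 was not matched either. H3K36me2 peaks outside the X block were also divided into 5 groups by fold. From the weakest to the strongest, the share on knockout H3K27me3 was 9.04%, 13.3%, 14.8%, 14.6% and 9.74%. It rose and then fell, so a steady rise with strength was not shown. Median width rose over these groups from 448 bp to 1232.5 bp and was not matched. The shares therefore cannot separate strength from width. With 1 list per genotype a loss of NSD1 cannot be told apart from a difference between the cell lines or their libraries.

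NSD1 peaks of mESCs were called with no control, so open chromatin alone could give peaks at enhancers. The NSD1-C list holds, by the way it was called, only sites over the knockout control (1995 peaks). Its length is therefore no separate test of background equal in that control. Background that differs between the rescue and knockout libraries cannot be told apart from binding there by the share on H3K27ac, since 77.1% would be high under either. Of the NSD1-C peaks, 54.7% also overlapped the EpiSC list, which was called against cells treated with dTAG-13. The cell state of that control could not be checked from the labels, and the remaining peaks have no second control, so the question stays open. For the NSD1 peaks of mESCs in no other NSD1 list, 40.5% of which lay on H3K27ac, binding and background cannot be told apart, because no list with a matched control covers them.

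A block on chromosome X, whose limits were set after its peaks were seen and which was densest from 124000001 to 124500000, held 83 H3K36me2 peaks with a median fold of 6.68, against 3.62 elsewhere. Of its peaks, 2.41% [0.293 to 8.43] overlapped NSD1, against 64.5% elsewhere. H3K27ac and BRD4 overlapped 0% of them and MED1 2.41%, so few peaks of other lists were called there. Missing NSD1 calls therefore cannot exclude NSD1 binding as the cause. A copy number difference between the lines and reads shared between near-identical gene copies could each give such a block and cannot be told apart. None of its peaks overlapped H3K4me1 (0%), and 11 of the 12 largest H3K36me2 folds on chromosomes 1 to 19 and X lay in it, which settles neither. No biological explanation beyond NSD1 binding was tested, and that test could not decide. Another stretch of X (94500001 to 95000000), counted as elsewhere, held 25 H3K36me2 peaks, of which 0 overlapped H3K4me1 and 2 NSD1.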

How the results depend on the processing

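Leaving out the strongest 1% of each list, the matched number of H3K27me3 peaks for results other than covered length, a q of 1e-06 or less for gene lists, every alternative of the H3K27ac shares and all tests of direction were chosen only after the results were seen. No paired analysis was possible because each group or pool gave 1 list and replicate numbers are not carried by the lists, and for the same reason leaving out a replicate was not possible.

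Over 33 tested results, 270 of 276 alternative values kept their direction and their side of the threshold. The overlap of mESC NSD1 peaks with gene ends at a q of 1e-06 or less is not counted, since that list was already called at this q. For the distal ratio, other placements altered only the random values it was compared with. NSD1 in mESCs on H3K27me3 turned from 1.25 to 0.915 with the stronger 50% of each list and to 0.886 with rotation by at most 1 Mb. H3K36me2 on knockout H3K27me3 turned from 1.04 to 0.898 with the stronger 50% of each list, to 0.747 with a q of 1e-06 or less and to 0.636 with rotation by at most 1 Mb. Knockout-only H3K27me3 on H3K36me2 weakened from 1.74 to 1.05 (permutation p = 0.4715) with that rotation. The cause was not tested.

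The covered length of H3K27me3, knockout over NSD1-dTAG, moved from 1.62 to 1.58 with a q of 1e-06 or less, 1.62 with every contig, 1.41 with the same number of peaks and 1.64 with intervals within 1 kb joined. The share of H3K27ac peaks with and without H3K36me2 on knockout H3K27me3 moved from 8.13% and 2.14% to 4.19% and 1.46% with 50% of the peak covered, 4.61% and 1.56% with the stronger 50%, 2.72% and 0.883% with a q of 1e-06 or less, and 6.12% and 1.61% with the same number of peaks. The cause of these shifts was not tested.

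Shares of gene lists moved beyond their interval in 6 cases with windows of 2.5 kb, and 138 did not. With the stronger 50% of peaks 23 moved and 121 did not, with a q of 1e-06 or less 14 moved and 66 did not, and with the same number of H3K27me3 peaks 0 moved and 32 did not, leaving out shares that a setting could not alter. Depth could not be varied, because the lists hold no reads.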

Other observations

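NSD1 was found near most genes in at least 1 cell state. Of 21631 protein-coding genes, 9087 carried NSD1 within 5 kb of an end in both mESCs and EpiSCs, 3419 in mESCs alone and 1272 in EpiSCs alone. MED1 peaks lay at gene ends at 25%, against 13.5% of BRD4 and 12.7% of H3K27ac peaks, and most H3K27ac peaks (61.5%) lay inside genes away from their ends.

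Single genes of the fixed lists differed widely in H3K27me3 length between the lists of NSD1-dTAG and knockout mESCs. Longer in the knockout were Sox4, a transcription factor gene (629 bp and 9763 bp), Zic5, a zinc finger gene (2642 bp and 11356 bp), Ttr, which encodes transthyretin (4386 bp and 16639 bp), and Aebp2, a Polycomb cofactor gene (780 bp and 8388 bp). Kdm2b, an H3K36 demethylase gene, was covered in the knockout list alone (6212 bp). Otx2, a transcription factor gene of the epiblast and forebrain (5937 bp), and Cd3e, a T cell receptor subunit gene (7581 bp), were covered in the NSD1-dTAG list alone. These genes were chosen after their values were seen. No explanation was tested for the values in this part.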
